A study of Rattus norvegicus with 5 samples.

How the data were processed

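Gene expression was measured in BRL-3A cells, a line from Buffalo rat liver, with one-colour Agilent arrays. Per the labels, the cells fell into 5 groups with 1 array each: a Tmub1 overexpression lentivirus, a Tmub1 knockdown lentivirus, a negative control virus for each of these, and normal cells with no virus. Total RNA was taken 48 h after transduction, and Cy3-labelled cRNA was made from 1 µg of it per the labels. The 4 transduced arrays were scanned on 1 day and the normal array on another. Batch and group therefore cannot be told apart in the comparisons with normal cells.

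The deposited scanner files hold, for each spot, a processed signal in intensity units that the scanner software had already background-subtracted and spatially detrended, with no scaling between arrays. Per the file headers, the spots were read with Agilent Feature Extraction 11.0.1.1; the submitters' processing notes name version 9.1. The deposited table of processed values is in log2 units and has 30423 entries; its 5 columns have the same quartiles and a median of 6.685 each, as quantile normalization leaves them. The software of that normalization is not given in the sources used here. The scanner software marked spike-in measures as out of range on all arrays, and it is not known whether spike-ins were used.

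For the main values, the log2 of each array's processed signal was taken. Control spots and spots that the software marked as poor were left out, and the replicate spots of a probe were averaged. This left 30367 probes, and the 75th percentile of each array's probe values was then subtracted. A probe was named when the accession in the array files was found in the RefSeq table for rat: 18005 probes had 1 gene and 12362 stayed unnamed, which does not mean that they have no gene. The 18005 probes fell on 15167 genes, 2600 of them with more than 1 probe, and each gene was read from its probe with the highest mean. The array was designed on an older genome build than that of the RefSeq table, so no positions are given.

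A gene was called higher or lower when its brighter value was well above background by the scanner software's call and the difference reached 2.5-fold, the fold named in the series' design text. A dimmer value below background was replaced by the array's lowest value well above background where that was higher, which makes the difference a lower bound. With 1 array per group there were no replicates, so no p-value is given for the comparisons and no call could be checked against a replicate; the p threshold of the design text could not be applied. The count of genes that far apart between the 2 negative controls is given as the background, which holds array noise and any difference between the 2 control viruses. The number of arrays limits the precision: the scanner software's error covers the spot reading alone.

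Gene lists covering 22 pathways and cell types, with 817 symbols, were fixed before the data were examined; 741 of the symbols were on the array. The median log2 difference of each list was placed among 10000 random lists of the same size matched on mean expression in 20 bins. A list was called outside the range when it lay in the outer 0.5% at either end. This percentile describes the arrays and is not a test of the conditions. A list's relative shift is its median minus that of the random lists. Markers of 11 tissues and developmental programs were added after the largest differences from normal cells had been seen. Members such as Ckm, Tnnc2, Hbb, Cd74 and Sncg were among those differences, so their values were known, and the remaining members were looked up afterwards. The exception is that fat and muscle formation were added once the muscle markers had been read.

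The rule for naming genes, the comparisons, the 2.5-fold threshold and most of the alternative settings were also fixed before the data were examined. Apart from Tmub1, the rule took up to 10 genes per direction that were well above background on all 5 arrays, past 2.5-fold against their own negative control and at least 1.5-fold from the other 2 controls in the same direction. It added up to 4 changed members per list and direction, up to 5 genes per kind of overlap and per direction after transduction, and up to 3 genes per direction known only by a bound. Genes with a placeholder symbol and large paralog families were not named.

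Alternatives were quantile normalization, cyclic loess, the 75th percentile over the 19481 probes above background on all arrays, normexp with an offset of 50, the authors' log2 table, other filters on dim probes, the mean of all probes of a gene, fold thresholds of 2 and 4, and other reference arrays. The files hold no mean pixel signal, so normexp used the median pixel signal, which the plan had not named. limma 3.58.1 was also run with the 3 control arrays taken as 1 group, an assumption that the labels do not make, and gives the only p-values. Requiring the threshold against both negative controls or each of the 3 controls, using all 4 transduced arrays, and leaving out the tissue markers were added after the data had been seen. R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.

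The calls were tested on simulated data with 15038 genes, 50 of them changed at each fold. With a spread like that between the 2 negative controls, 16% of genes changed 2-fold, 56% of those changed 3-fold, 84% of those changed 4-fold and 100% of those changed 8-fold were called, with 819 unchanged genes called (6.23%). With the scanner error alone, 6%, 90%, 100% and 100% were called and no unchanged gene was. A list raised by 0.5 log2 came out at percentile 100, and 0 of 22 unchanged lists fell outside the range. The changed genes and the lists were drawn without the dimmest genes. Each gene varied on its own, so lists of genes that vary together were not simulated. Between the 2 real negative controls, 8 of 22 lists fell outside the range.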

Results

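The series asks how Tmub1, a transmembrane protein with a ubiquitin-like domain, affects transcription in hepatic cells. It holds 5 arrays of BRL-3A rat liver cells, 1 per group: overexpression, knockdown, the negative control of each virus, and normal cells. Each array gave 42877 non-control spots and no saturated spot. The median processed signal was 143.9 with overexpression, 356.2 with knockdown, 116.4 and 159.7 in the overexpression and knockdown negative controls, and 329.4 in normal cells. Probes well above background made up 72.4%, 80.9%, 67%, 73% and 86.6% of all probes in the same order. The replicate spots of a probe varied by a median of 5.07% to 5.71% within an array.

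Tmub1 mRNA was 3.65-fold lower with the knockdown virus than in its negative control, a log2 difference of -1.87 with a 95% interval from scanner error of -2.27 to -1.47. It was 3.44-fold lower than in the other negative control and 2.83-fold lower than in normal cells. With the overexpression virus the Tmub1 signal lay at 1.05-fold its negative control, a log2 difference of 0.07 (-0.33 to 0.47), so a rise was not detected. The gene has 1 probe on the array, A_64_P114198, and whether it sees the transcript carried by the virus is not given in the sources used here. Its normalized log2 value was 0.44 with overexpression, -1.42 with knockdown, 0.37 and 0.45 in the negative controls of overexpression and knockdown, and 0.08 in normal cells. The 3 control arrays spanned 1.29-fold for this gene.

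**Figure D1:**
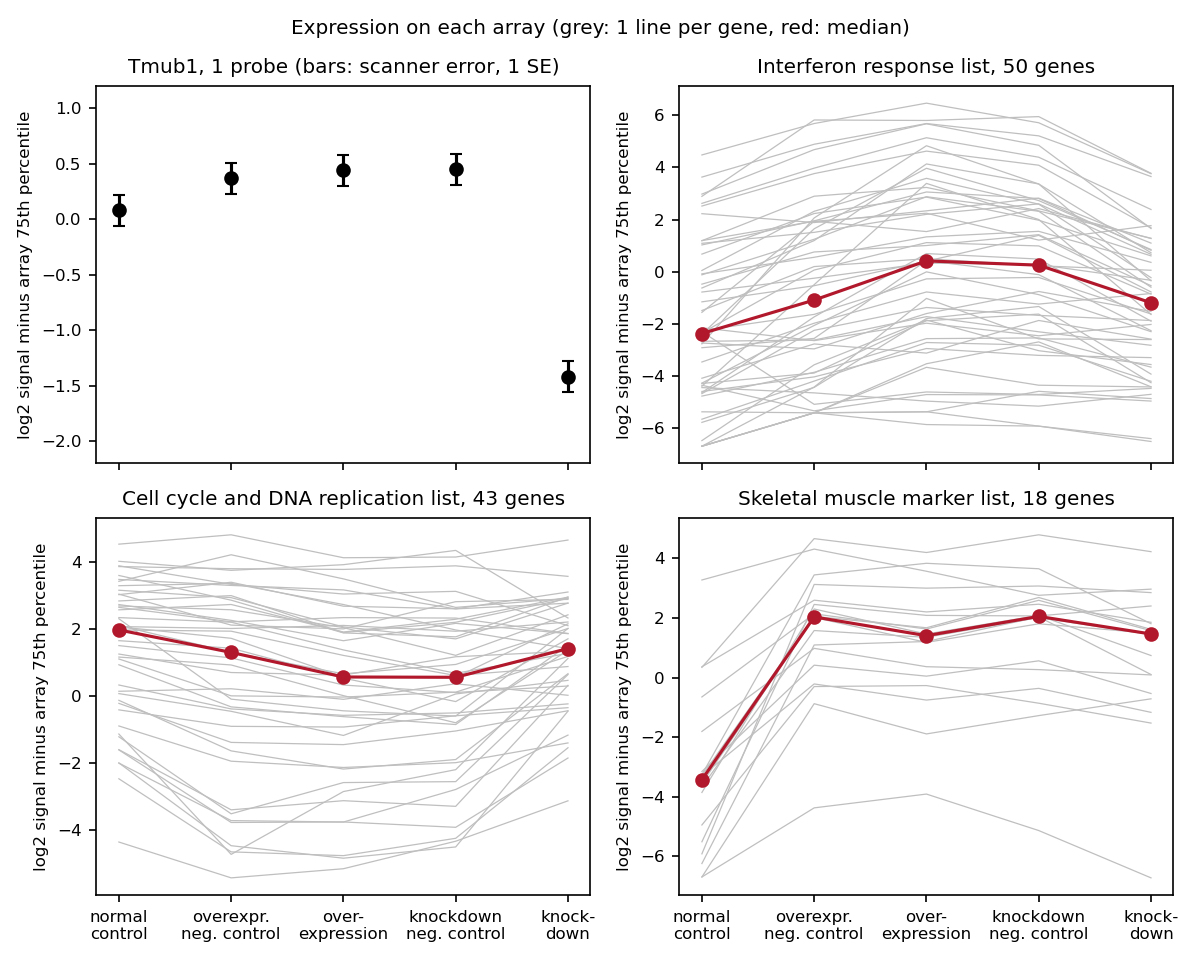
Normalized log2 values on each of the 5 arrays for Tmub1, with 1 SE of the scanner error, and for the genes of the interferon response, cell cycle and skeletal muscle lists, with grey lines for genes, red for the median and dim values set at the array's floor. Tmub1 was at -1.42 with knockdown; the interferon median was 0.42 with overexpression and -1.19 with knockdown, and the muscle median was -3.43 in normal cells.

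The overexpression virus was compared with its negative control to ask which genes differ when cells carry the Tmub1 vector. Interferon-induced antiviral genes were higher: Isg15, a ubiquitin-like protein induced by interferon, was 14.7-fold higher, the antiviral Ifit3 10.5-fold, Oasl2 7.91-fold, the transcription factor Irf7 7.66-fold and Rsad2, an inhibitor of viral replication, 6.81-fold. The chemokine Cxcl10 was 4.99-fold higher. In the NF-kB and inflammation list, which lay inside the range of random lists, the chemokines Cxcl2, Ccl20, Cxcl1 and Ccl3 were 6.23-, 3.70-, 2.81- and 2.64-fold lower and Nfkb2 was 2.52-fold higher, of 30 genes measured. Against the other negative control Isg15 was 2.61-fold, Cxcl10 2.36-fold, Irf7 1.70-fold and Oasl2 1.45-fold higher, and Cxcl2, Ccl20, Ccl3 and Nfkb2 had log2 differences of -0.85, -0.72, -0.16 and -0.38. In all, 202 genes were at least 2.5-fold higher and 119 lower, of 11851 that could be called.

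Of the 49 measured interferon response genes, 17 were higher and 0 lower with overexpression, and the list median was 0.99 log2 up, above all 10000 random lists. Against the knockdown virus's negative control the same list was shifted by 0.25 relative to random lists, with 3 genes higher and 0 lower, and still lay above the range. Cell cycle and DNA replication genes had a median of -0.31, below all random lists, although only Rrm1, the large subunit of ribonucleotide reductase, passed the threshold, at 3.65-fold higher, and it stood at -0.65 log2 against the other negative control. That list's relative shift went from -0.28 to -0.12, inside the range, against the other negative control, and was -1.31 against normal cells with 13 genes lower. Centrosome and mitotic spindle genes had a median of -0.34, with 0 of 15 past the threshold, and its relative shift against the other negative control was 0.23, also inside the range, and -1.05 against normal cells. Ubiquitin and proteasome genes had a median of 0.14 with 1 of 49 higher, the same Isg15, and were inside the range against every other reference and against random lists not matched on expression.

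Macrophage and leukocyte markers had a median of -0.43 with overexpression, with 0 of 16 past the threshold, and came inside the range against every other reference and, at -0.33, with probes above background on all arrays. The skeletal muscle and fat markers described later had medians of -0.39 and -0.56. The other 17 lists lay within the range of random lists. Among their members, the growth factor response gene Phlda1 was 5.99-fold higher and the transcription factor Mycn 3.16-fold lower. In the endoplasmic reticulum list, the chaperone Pdia4 was 5.29-fold higher. Selenok in that list was 26.0-fold higher, its probe being low on the negative control array alone. The protease inhibitor A2m, of the interleukin 6 list, was 9.13-fold lower, with a log2 difference of -3.19 on its main probe and -3.33 on the other. Fgf21, a liver hormone of the ATF4 list, was 3.98-fold lower, the progenitor marker Dlk1 3.62-fold lower and the fetal liver protein Afp at least 2.93-fold lower. Several of these rest on the overexpression negative control array: against the knockdown virus's negative control the log2 difference was 0.05 for Selenok, -0.82 for Mycn, -0.68 for Phlda1, -0.41 for Pdia4, -0.51 for A2m and 0.60 for Dlk1. For Afp no difference could be read there, as it was below background on both arrays.

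The interferon-induced nucleotide kinase Cmpk2 was 4.15-fold higher, and 1.83-fold against the other negative control. Beyond the lists, among genes above background on all 5 arrays and apart from all 3 controls, Mlana, a melanosome protein, was 13.8-fold higher, Rtp4 6.98-fold, the vesicle traffic gene Scfd2 5.65-fold, Haao 4.88-fold and Sult1c2 3.59-fold. Among these genes the largest decreases were in Pnoc, the precursor of nociceptin, at 5.36-fold, in S100a9, a calcium-binding protein of inflammation, at 4.54-fold, and in the melanosome transporter Slc45a2 at 4.39-fold. Sez6l2, Myocd, Abcc8 and Spmap2 were 3.04- to 3.17-fold lower. Sult1c2, Slc45a2 and Myocd fell short of the threshold against the other negative control, at 1.19, -0.74 and -0.99 log2. Of genes known only by a bound, Padi6 was at least 61.9-fold higher, and Mdc1 at least 59.9-fold, the latter with a log2 difference of -0.26 against the other negative control. Ttc9b was at least 6.78-fold, Fgf20 at least 6.09-fold and Lhx1 at least 5.59-fold lower. Against the other negative control no difference could be read for these genes, as they were below background on both arrays. The scanner error of the log2 differences of Rtp4, Pnoc and S100a9 was 0.06, 0.20 and 0.34.

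The overexpression count was below the background: the 2 negative controls differed at least 2.5-fold in 1017 of 11922 genes (8.53%), against 321 (2.71%) for overexpression. Any difference between the 2 control viruses adds to that background. It therefore does not show that the overexpression count lies below array noise. Of these 321 genes, 87 (27.1%) differed in the same direction by at least 1.5-fold from the knockdown virus's negative control as well, and 40 higher and 18 lower genes passed 2.5-fold against both negative controls. The share of changed genes that were higher was 62.9%, against 49.4% with normexp and 51.7% in the authors' values.

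The knockdown virus was compared with its negative control to ask which genes differ when Tmub1 is reduced. Genes of cell division were higher: the mitotic kinase Aurkb by 16.4-fold, the spindle factor Tpx2 by 12.1-fold, Rrm1 by 9.92-fold, the centrosome kinase Nek2 by 9.48-fold and the replication helicase subunit Mcm6 by 9.09-fold. In the NF-kB and inflammation list, the chemokines Ccl7 and Ccl20 were 11.2- and 10.0-fold higher and the prostaglandin synthase Ptgs2 14.1-fold, among 10 of 34 genes higher. Antiviral interferon-induced genes were lower: Rsad2 by 13.1-fold, Isg15 by 12.5-fold, Mx2 by 9.12-fold and Ifi44 by 7.52-fold. Stat3, the transcription factor of interleukin 6 signalling, was 4.53-fold lower and the cell cycle inhibitor Cdkn1a 3.25-fold lower, although Cdkn1a was 1.87-fold lower than the other negative control and 0.05 log2 from normal cells. In all, 1079 genes were higher and 1284 lower of 12785 that could be called (18.5%).

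The median over all genes was -0.25 log2 with knockdown, so list shifts are given relative to random lists. Of 43 cell cycle and DNA replication genes, 13 were higher and 1 lower, with a relative shift of 0.99, and against the other negative control the shift was 0.81. The cyclin-dependent kinase phosphatase Cdc25b was the lower one, at 4.03-fold, while its other probe gave a log2 difference of -0.44. The relative shift of the list was 0.12 against normal cells, inside the range. The list medians themselves were 0.60, 0.28 and -0.09 log2 against its own negative control, the other negative control and normal cells. Of 16 centrosome and spindle genes, 4 were higher, among them Kif23 at 5.19-fold and Kif2c at 3.08-fold, and Nedd1 was 3.19-fold lower. The median of this list was 0.76, outside the range, while its relative shift against the other negative control was 0.23, inside it. In the p53 and cell cycle inhibitor list, 6 genes were higher and 5 lower, and the list lay inside the range. Pmaip1 at 6.63-fold and Gadd45g at 5.97-fold were higher, and Btg1 at 4.08-fold was lower, with 2.09-fold against the other negative control and 0.07 log2 against normal cells.

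Of 49 interferon response genes, 27 were lower and 0 higher with knockdown, and the median of -1.40 was below all random lists, a relative shift of -1.11. Against the other negative control the relative shift was 0.16, inside the range, with 2 genes higher and 12 lower; Mx2 stood at -3.02, Rsad2 at -2.41, Ifi44 at -1.84 and Isg15 at -1.14 log2 there. Against normal cells the shift was 0.83, the reverse direction. The higher NF-kB and inflammation genes included Mmp3, a matrix protease, at 9.16-fold, and 1 gene was lower, Nos2 at 3.38-fold; the relative shift was 0.76. It came inside the range with normexp, at 0.28, and with probes above background on all arrays, at 0.36. In the interleukin 6 and STAT3 list, 1 gene was higher, the receptor Osmr at 3.71-fold, and 5 were lower, among them the signalling inhibitor Socs1 at 3.96-fold and Tmub1 itself. Against the other negative control Socs1 had a log2 difference of 0.16.

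Of 43 endoplasmic reticulum stress and degradation genes, 6 were higher and 3 lower, with a relative shift of 0.60; the chaperones Canx and Pdia4 were 5.33- and 5.06-fold higher, and Hyou1 and Dnajb9 were 4.55- and 4.53-fold lower. Tmub1 was the remaining lower member. The call ended with cyclic loess, at 0.40. Of 35 ATF4 amino acid response genes, 7 were higher, with Sesn2 at 4.34-fold and the amino acid transporter Slc1a4 at 3.85-fold, and the cystine transporter Slc7a11 was 2.66-fold lower. The ATF4 shift was 0.50, although the list median itself was -0.01 log2. The endoplasmic reticulum median was 0.18 log2. Both shifts thus rest largely on the lower values of the random lists. Both calls ended against random lists not matched on expression. The endoplasmic reticulum and ATF4 shifts against the other negative control were 1.26 and 1.15, and against normal cells 0.76 and 1.99, above all random lists each time. The list medians themselves were 0.67 and 0.44 log2 against the other negative control, and 0.50 and 1.67 against normal cells.

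The 16 remaining lists, the p53 and interleukin 6 lists among them, lay inside the range of random lists in knockdown. Immediate early and growth factor genes went both ways, 8 higher and 7 lower: the growth factor Hbegf was 14.6-fold, the signalling inhibitor Spry2 11.9-fold and the matrix protein Ccn2 7.68-fold higher, and Jund, Ier5 and Junb were 3.98-, 3.91- and 3.15-fold lower, although the other Ier5 probe gave a log2 difference of -0.11. The immediate early list lay above the range against the other controls, with relative shifts of 0.83 against the other negative control and 1.45 against normal cells. In the extracellular matrix and TGF-beta list 9 genes were higher and 4 lower. Tagln, an actin-binding protein, was 7.06-fold higher, and the membrane protease Mmp14 was 6.43-fold lower. Insulin-like growth factor genes included Igf1r at 3.76-fold higher and Igfbp1 at 4.10-fold lower and the growth factor Igf2 at a log2 difference of -1.58, with 2 genes higher and 4 lower in all. Apoptosis genes were 3 higher and 6 lower, with Casp8 at 3.66-fold higher and Bmf at 6.01-fold lower.

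In metabolism, 4 cholesterol and fatty acid synthesis genes were higher and 0 lower, Sc5d at 4.61-fold and Nsdhl at 3.78-fold. In glycolysis and hypoxia 4 were higher and 3 lower, among them P4ha2 at 4.29-fold higher and the glycolytic enzyme Pfkp at 6.94-fold lower. Genes of NRF2 and oxidative stress were 1 higher and 6 lower, with Taldo1, an enzyme of the pentose phosphate pathway, 4.64-fold lower. Heat shock proteins were 1 higher and 4 lower, and ubiquitin and proteasome genes 1 higher and 5 lower, with Uchl1 3.99-fold lower. Against the other negative control the glycolysis, NRF2 and ubiquitin lists lay above the range, with relative shifts of 0.75, 0.62 and 0.85. Their list medians themselves were 0.14, -0.19 and -0.15 log2 there. Against normal cells the NRF2 and heat shock lists lay above the range, at 0.61 and 0.67, and the glycolysis and ubiquitin lists inside it.

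Hepatocyte markers were 4 higher and 5 lower with knockdown: Arg1, an enzyme of the urea cycle, was 8.32-fold higher, though only 1.94-fold against the other negative control and 0.58 log2 against normal cells, and Ahsg, a secreted liver protein, was 6.24-fold lower. The hepatocyte markers were dim, with a median level of -5.01 with knockdown and -5.26 in its negative control. Of 38 such genes, 29 and 23 were well above background on these arrays. Among cholangiocyte and progenitor markers 2 were higher and 1 lower, Krt19 at 5.99-fold lower. Stellate cell and fibroblast markers were 3 higher and 2 lower, with Pdgfrb 4.19-fold lower. Endothelial markers were 1 higher, Tek at 3.22-fold, and 1 lower, Erg at least 6.29-fold. Of the macrophage and leukocyte markers only Mrc1 passed, at least 3.05-fold lower. The skeletal muscle and fat markers described later had medians of -0.64 and -0.94 log2 in this comparison.

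Outside the lists, among genes above background on all 5 arrays and apart from all 3 controls, the largest increases with knockdown were in P4ha3, a collagen prolyl hydroxylase, at 52.0-fold, in Edn1, the precursor of endothelin, at 39.7-fold, in the interleukin 33 receptor Il1rl1 at 23.3-fold and in the anchoring protein Akap5 at 20.4-fold. Akap5 was 2.61-fold above the other negative control and 1.51-fold above normal cells. Ankrd1 and the transcription factor Tead1 were each 18.3-fold higher, Serpinb2 16.7-fold and Pask 14.6-fold. Of genes known only by a bound, the cytokine Il24 was at least 26.6-fold higher, and Txndc9 at least 136-fold, its probe being dim on the knockdown virus's negative control array alone and the difference from the other negative control being -0.46 log2. Lower were Styxl1 at least 78.9-fold and Arl6ip6 at least 20.5-fold lower. Among genes above background on all arrays, the largest decreases were in the Notch-induced repressor Hey2 at 53.1-fold, Pnoc at 21.2-fold, the alkaline phosphatase Alpl at 15.6-fold, Slc25a42 at 14.6-fold, Aldh6a1 at 12.4-fold, the transcription factors Runx1, Hoxd10 and Prdm1 at 11.7-, 10.5- and 10.1-fold, Sipa1l2 at 10.1-fold and Ism1 at 9.74-fold. The other Hey2 probe gave a log2 difference of -2.50, against -5.73 on the main probe, and the other Il1rl1 probe gave 1.44, against 4.54.

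Of the 2363 genes called with knockdown, 2185 (92.5%) differed in the same direction by at least 1.5-fold from the other negative control too, and 1645 by at least 2.5-fold. Both comparisons use the same knockdown array, so their agreement is no check on the values of that array. Other named genes that fell short of 2.5-fold against the other negative control included Ccn2 and Nsdhl, 2.21- and 2.16-fold higher. Junb, Nos2, Pdgfrb and Slc7a11 did so too, at 2.45-, 2.38-, 2.27- and 1.81-fold lower. Mrc1, known only by a bound, did not reach 2.5-fold there either. The direction split depended on the scaling: 45.7% of called genes were higher, against 56.6% with cyclic loess, 71.2% with the 75th percentile over detected probes and 34.1% with normexp. Among called genes with another probe, the other probes differed by at least 1.5-fold in the same direction for 190 of 411 with knockdown and 15 of 28 with overexpression, and went the opposite way for 125 and 6.

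Between the negative controls, neither of which carries a change in Tmub1 by its label, 400 genes were higher and 617 lower in the overexpression control. Interferon response genes had a median of -0.82 there, 12 lower and 0 higher. Endoplasmic reticulum genes had a median of -0.44, ATF4 genes -0.43, p53 and cell cycle inhibitor genes -0.75, and immediate early genes -0.37. Heat shock and ubiquitin lists were also below the range, and centrosome and spindle genes above it at 0.71. In all, 8 of 22 lists were outside the range between these arrays, against 5 for overexpression and 6 for knockdown. The share of changed genes that were higher was 39.3%, against 53.8% with normexp.

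**Figure D2:**
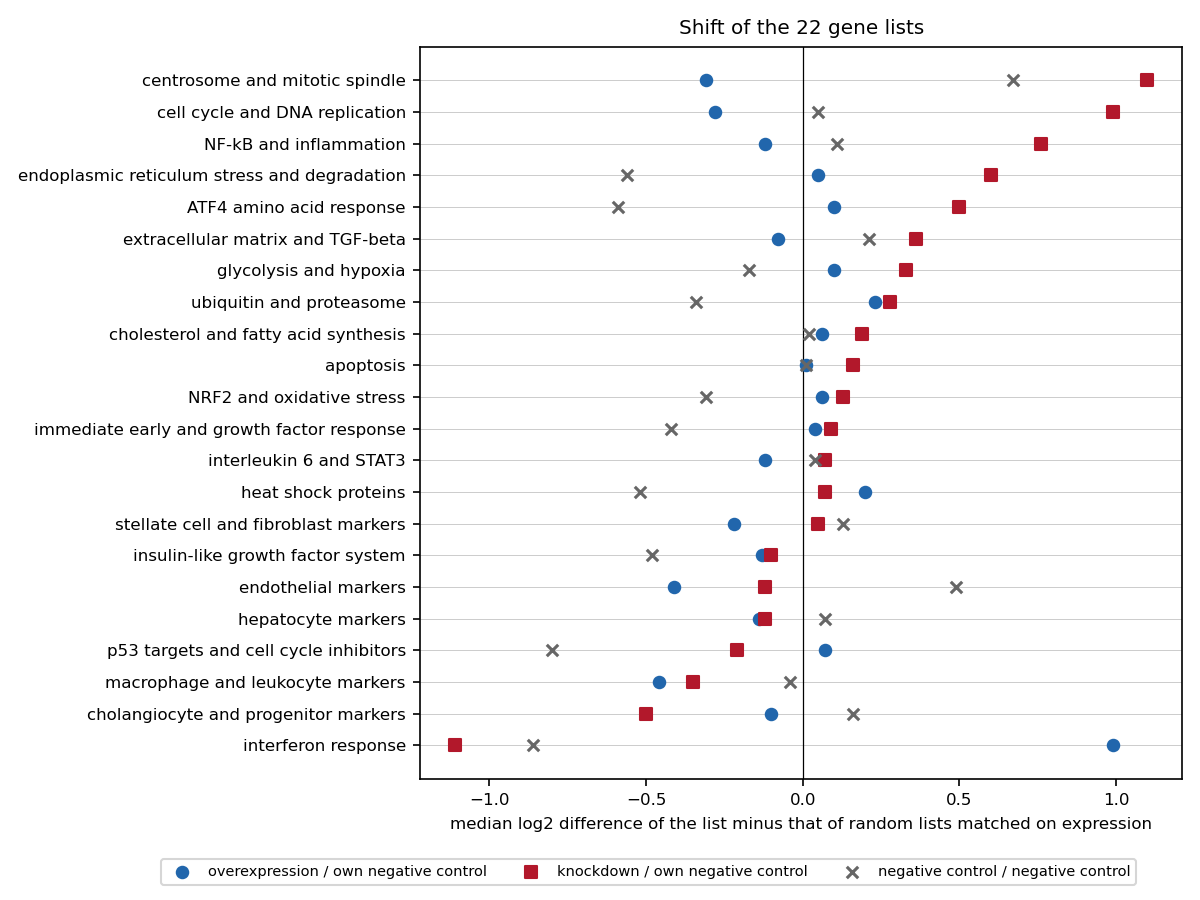
Median log2 difference of each of the 22 gene lists minus that of expression-matched random lists, for overexpression (circles) and knockdown (squares) against their own negative controls and for the negative controls against each other (crosses). Interferon response genes lay at 0.99, -1.11 and -0.86 in that order, and cell cycle genes at -0.28, 0.99 and 0.05.

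The lists of genes changed by both viruses were compared to ask whether the overexpression and knockdown viruses moved genes in opposite ways, with Tmub1 itself lower in knockdown and not detectably raised with overexpression. Isg15, Rsad2, Mlana and Rtp4 were higher with overexpression and lower with knockdown, Mlana by 8.27-fold and Rtp4 by 7.97-fold in knockdown. Cxcl2 was lower with overexpression and 7.46-fold higher with knockdown. Knockdown against the other negative control was 1.57-fold lower for Mlana, 2.21-fold lower for Isg15 and 2.16-fold higher for Cxcl2, all short of the threshold. In all, 37 genes were higher with overexpression and lower with knockdown, where independent lists would share 19.7, and 13 of these were interferon response genes. A further 24 were lower with overexpression and higher with knockdown, where 8.88 would be shared. Pdia4, Arhgap29 and Chuk, a kinase of NF-kB signalling, were among 26 genes higher in both, where 15.7 would be shared; Arhgap29 was 4.08- and 6.85-fold and Chuk 3.68- and 3.90-fold higher. With overexpression against the other negative control, the log2 difference was -0.41 for Pdia4, 0.05 for Arhgap29 and 0.64 for Chuk. Pnoc and S100a9 were among 5 genes lower in both, where 11.2 would be shared. Across the 10790 genes measured in both, Pearson's r of the log2 differences was -0.007, and it was -0.462 over 44 interferon genes; genes are not independent replicates.

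Each negative control was compared with normal cells to ask what carrying a virus changed. Genes far higher in both included Ckm, the muscle creatine kinase, by 526- and 508-fold, the muscle troponin Tnnc2 by 250- and 191-fold, the beta-globin Hbb by 217- and 227-fold on its main probe, the antigen presentation gene Cd74 by 209- and 192-fold, and Sncg, a synuclein of neurons and fat, by 170- and 366-fold. Keratin Krt17 was 13.1- and 54.2-fold lower, the cell cycle regulator Mxd3 8.86- and 7.44-fold, C1h11orf86 6.81- and 9.60-fold, and Dhcr7, an enzyme of cholesterol synthesis, 5.99- and 7.24-fold. In all, 571 genes were higher in both negative controls than in normal cells and 585 lower. Unchanged groups sharing 1 normal array gave at most 116 and 113 in 100 simulations. The simulated noise came from the spread between the 2 negative controls, scanned on 1 day, so it holds no difference between scan days. An excess over the simulations therefore cannot be told apart from such a difference. The simulations also set no floor for dim values. Of the real lower calls, 388 in the overexpression and 346 in the knockdown negative control were bounds set by the floor. The lower count was 154 with quantile normalization, 92 with cyclic loess and 43 with normexp, so its excess over the simulations rests on the scaling. The other Hbb probe gave a log2 difference of 1.77 in the knockdown negative control, and the other C1h11orf86 probe gave -0.02 and -0.70.

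Interferon response genes had medians of 1.25 and 2.07 log2 above normal cells in the overexpression and knockdown negative controls, and 20 were higher in both. Cell cycle genes had medians of -0.49 and -0.99, with 7 lower and 0 higher in both. Cholesterol and fatty acid synthesis genes were at -0.62 and -0.71, ATF4 genes at 0.93 and 1.41, immediate early genes at 0.78 and 1.46, and macrophage and leukocyte markers at 0.57 and 0.64. All of these lay outside the range of random lists.

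Markers of skeletal muscle were higher than in normal cells by at least 2.5-fold on all 4 transduced arrays for 16 of 18 measured genes (88.9%), and the median of the list was 4.92 log2 above normal cells in the negative controls. The alpha-actin Acta1 was at least 81.2-fold, Ckm at least 435-fold and Tnnc2 at least 191-fold above normal cells on every transduced array. All 6 fat markers were higher on all 4 arrays, among them Adipoq, Fabp4 and Cfd. Of antigen-presenting cell markers 4 of 10 were higher, of nervous tissue markers 3 of 11, of red blood cell markers 1 of 9, Hbb, with a list median of -0.73 log2 in the negative controls over normal cells, of liver markers 1 of 7 and of muscle formation markers 1 of 7, and 0 heart, pancreas, kidney and testis markers were. These tissue markers were chosen after the largest differences had been seen, Ckm, Tnnc2 and Hbb among them. Without them, 536 genes were higher and 582 lower in both negative controls.

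The comparisons with normal cells depended on the scaling, and the scan day of the normal array was its own. In the overexpression negative control 43.3% of changed genes were higher than in normal cells, against 71.4% with quantile normalization, 74.8% with cyclic loess, 24.4% with the 75th percentile over detected probes, 81.7% with normexp and 70.7% in the authors' values. In the knockdown negative control the share was 42.6%, against 70.0%, 74.6%, 29.7%, 71.8% and 67.5% in the same order.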

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

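The tests of the interferon and cell cycle patterns, of muscle with fat and of the scan day were chosen only after the result had been seen. The muscle formation test was chosen once the muscle markers had been read, before the values of its own genes were, and the whole tissue test before either, with the values of Ckm, Tnnc2 and Hbb already seen.

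Data outside the named genes were flagged by the signal they held. Among 9530 probes without a gene name here, 1534 (16.1%) differed at least 2.5-fold with knockdown, against 643 of 8406 (7.65%) between the 2 negative controls. Both shares were below those of the named genes, 18.5% and 8.53%.

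Interferon response genes were higher with overexpression and lower with knockdown than in their own negative controls. Scaling does not account for it, since the smallest relative shift over 5 other scalings was 0.86 with overexpression and -0.78 with knockdown, outside the range of random lists in every one. A difference between the 2 negative control arrays fits the shift of the list in both parts, though not every member: against the other virus's negative control it was 0.25 with overexpression, still just above the range, and 0.16 with knockdown, inside it, where 12 genes stayed lower and Mx2 stood at -3.02 log2. Whether more Tmub1 could take part cannot be told apart, as Tmub1 mRNA stood at 0.07 log2 above its control and it is not known whether its probe sees the introduced transcript. The list stood above normal cells on all 4 transduced arrays, a comparison in which virus and scan day cannot be told apart. The opposite directions may come from how strongly each virus stock raised these genes, which was not tested.

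Cell cycle genes were higher with knockdown than in its negative control. Scaling does not account for it, as the smallest relative shift over 5 other scalings was 1.00. Against the other negative control the relative shift was 0.81, with 11 genes higher and 2 lower. The list median itself was 0.28 log2 there, against 0.60 over its own negative control. The list's level was 1.41 with knockdown, and 1.30 and 0.56 in the overexpression and knockdown negative controls. A low level on the knockdown virus's negative control alone therefore cannot be excluded, as the answer depends on the measure. Knockdown stood at 0.12 relative to normal cells, inside the range of random lists, and both negative controls below them. That fits a smaller distance below the normal level rather than a rise past it. An effect of transduction on that level cannot be told apart from the normal array's own scan day. Nor can it be told apart from whatever brought muscle and fat transcripts to the transduced arrays. Less Tmub1 stays open as a biological explanation beside a difference in virus dose or cell density, and 1 array per group tests none of these.

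Transcripts of skeletal muscle and fat, with some genes of other tissues such as Hbb, were far above normal cells on all 4 transduced arrays. A muscle formation program switched on in the cells is argued against by its own genes, of which 14.3% were higher on all 4 arrays, although that 1 gene, Myh8, was at least 274-fold above normal cells on each. RNA of muscle with its fat mixed into the transduced samples fits, with 88.9% of skeletal muscle genes and all 6 fat genes higher, and could act at any step before labelling. RNA of whole tissue with its blood was predicted to raise most red blood cell genes too, but 11.1% were higher, so that part was not met. The rule of this test could not go against whole tissue while the muscle genes were high. The probe of the alpha-globin Hba-a1 also stood at a normalized log2 value of 4.90 in normal cells already. No conclusion on whole tissue is therefore drawn from it. An intensity trend between scan days is argued against by the other scalings, under which at least 83.3% of muscle genes stayed higher, while anything else that went with the day, such as sample handling, cannot be told apart from the groups, with 0 of 4 transduced arrays scanned on the normal array's day.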

How the results depend on the processing

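The reference settings that ask for both negative controls or each of the 3 controls, the count over all 4 transduced arrays and the one without tissue markers were chosen only after the data had been seen. No paired analysis was possible because each group has 1 array. Normexp used the median pixel signal in place of the mean one. Tmub1 stayed between -0.01 and 0.36 log2 with overexpression and between -1.98 and -1.50 with knockdown under every alternative; averaging its probes moved nothing, as it has 1. Dim signal limits the calls: 67% to 86.6% of probes were well above background. Where no cause is given below, the cause was not tested.

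Values that moved by over 1.5 times are given by setting, with the reported counts of 202 higher and 119 lower with overexpression, 1079 and 1284 with knockdown, 1017 between the negative controls, 61 in opposite and 31 in the same direction, and 571 higher and 585 lower in both negative controls than in normal cells. The count lower than in normal cells was 154 with quantile normalization, 92 with cyclic loess and 170 in the authors' values. It was 348 with only probes above background on all arrays, where fewer genes were tested. With the 75th percentile over detected probes it was 1056, knockdown gave 1691 higher and 685 lower, and 49 genes changed in the same direction.

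With normexp, overexpression gave 38 higher and 39 lower and knockdown 486 higher. The negative controls differed in 385, 30 genes changed in opposite directions and 4 in the same one, and 321 were higher and 43 lower than in normal cells. With no filter and no bound, which admits dim probes, overexpression gave 434 and 315, the negative controls 1558, the opposite and same directions 112 and 96, and 1308 were lower than in normal cells.

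A lower threshold of 2-fold gave 459 and 260 with overexpression, 1716 and 2312 with knockdown, 1975 between the negative controls, 147 and 136 in opposite and same directions, and 866 and 1298 against normal cells. The stricter 4-fold threshold gave 46 and 28, 382 and 302, 271, 13 and 3, and 331 and 89 in the same order.

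Against the other virus's negative control, overexpression gave 261 lower and knockdown 1691 higher and 2002 lower. Against normal cells, overexpression gave 981 and 1267 and knockdown 2653 lower. Against the mean of the 3 controls, overexpression gave 76 lower. limma with the 3 controls as 1 group gave 58 higher and 38 lower with overexpression and 812 lower with knockdown at an unadjusted p under 0.05. With the adjusted p it gave 1 and 0 with overexpression and 0 and 0 with knockdown. The settings added later can only shorten the lists. At least 2.5-fold from both negative controls were 40 higher and 18 lower with overexpression and 835 lower with knockdown, and from each of the 3 controls 32 and 11, and 562 and 384. On all 4 transduced arrays 374 genes were higher than in normal cells.

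The lists outside the range with overexpression numbered 8 with quantile normalization, 8 in the authors' values and 3 against the mean of the 3 controls, from 5. The interferon list in knockdown reversed against normal cells, with a relative shift of 0.83. Of the alternatives in scaling or filter, 34 kept and 1 lost the call of a list outside the range with overexpression, and 39 kept and 3 lost it with knockdown. Against random lists not matched on expression, 4 kept and 1 lost it with overexpression, where the ubiquitin and proteasome list came inside at 0.13 and endothelial markers left the range at -0.33. With knockdown 4 kept and 2 lost it, the endoplasmic reticulum and ATF4 lists at 0.39 and 0.21. Of those in reference, 7 kept and 8 lost it with overexpression, and 11 kept, 6 lost and 1 reversed it with knockdown. Lists inside the range left it in 10 alternatives of scaling or filter and 9 of reference with overexpression, and in 3 and 11 with knockdown.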

Other observations

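The YAP/TEAD and MAPK tests were chosen before the result of either list had been seen, after the largest knockdown genes had been read. Their members were not all unseen, as some belonged to lists already scored in the same comparison. Among the MAPK genes, Phlda1, Spry4, Spred1, Dusp4, Dusp5, Dusp6 and Fosl1 were in the immediate early list. Ccnd1 was in the cell cycle list. Among the YAP/TEAD targets, Ccn1, Gadd45a, Igfbp3 and Tgfb2 were in such lists. The values against other arrays and the globin values were looked up afterwards, and the members named were picked once their values were known.

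Of 14 measured targets of YAP and TEAD, a coactivator and its transcription factors in the Hippo pathway, 5 were higher with knockdown than in its negative control, beside Ankrd1 and Ccn2. Amotl2, a YAP regulator, had a log2 difference of 3.46, and the kinase Nuak2 was 8.82-fold higher, the matrix protein Ccn1 4.27-fold, the receptor tyrosine kinase Axl 3.40-fold and Asap1 2.57-fold. Of these, Ccn1 fell short of the threshold against the other negative control, at 0.67 log2. The hypothesis of a general rise was prompted by Ankrd1, Ccn2 and Tead1 and tested on these 14, which leave out Ankrd1 and Ccn2. Their median was 0.81 log2, at percentile 100 of matched random lists, with 5 higher and 0 lower, which is consistent with that rise. Against the other negative control the median was 0.90, with 6 higher and 3 lower, among the latter the binding protein Igfbp3 and the growth factor Tgfb2. Against normal cells it was 1.04, with 5 higher and 1 lower. With overexpression the same genes stood at percentile 68.47, inside the range.

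The same question for genes that report MAPK signalling came out negative against the knockdown virus's own negative control, and the values differed against the other control arrays. It was prompted by higher Spry2, Hbegf and Dusp1, the last at 7.55-fold, in knockdown. The 12 other measured genes had a median of -0.78 log2, at percentile 2.63, with 0 higher and 3 lower: Etv5 at 3.56-fold, Spry4 at 3.15-fold and Dusp5 at 2.64-fold. These values argue against a general rise over that control. Against the other negative control the median of the 12 genes was 0.43, at percentile 94.35, with 3 higher and 0 lower. Etv5, Spry4 and Dusp5 stood at -1.1, -0.38 and 0.3 log2 there. Against normal cells the median of 13 genes was at percentile 99.96, with 5 higher and 0 lower, among them Etv5, Etv4 and Dusp6 at 2.93, 2.52 and 2.39 log2. The sign therefore depended on the control array.

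The alpha-globin gene Hba-a1 had normalized log2 values of 3.19 with overexpression, 3.65 with knockdown, 4.93 in the overexpression negative control and 4.90 in normal cells, and -1.42 in the knockdown negative control. Hbb stood at 1.17, 0.77, 1.66 and 1.72 on the overexpression, knockdown, overexpression control and knockdown control arrays and at -6.10 in normal cells.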
